A study of Homo sapiens with 6 samples.

How the data were processed

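RNA of human cord blood CD34+ cells, cultured in medium with 10% serum and 100 ng/mL of each of 3 cytokines per the labels' protocols, was sequenced after 16 h with riociguat or DMSO, 3 samples per group. Samples were assigned to groups and replicate numbers from their titles. No label says whether the samples came from separate donors or cultures, so the p-values measure only the spread between these samples, which may be partly technical.

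The authors deposited 1 table of genes with raw read counts per sample, per the file headers. The submitters' processing notes name STAR 2.5, featureCounts of Subread 1.5.1, edgeR 3.20.8, bcl2fastq and the hg38 genome, with no role for each. The annotation release and the strand setting are not given in the sources used here. The table held 18727 genes, each with at least 13 reads over the 6 samples. Of its versioned gene identifiers 16551 were found in GENCODE 29, each with the same start and end, and 18636 were found without the version. The deposited log2 fold changes and mean log2 CPM, and the deposited p-values with their FDR, are the authors' own results per the file headers, and they were compared with the results computed here. Another 6 columns of log2 CPM per sample were not used. The 20 genes on the Y chromosome, XIST and TSIX were left out of every step, which left 18707.

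Counts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, TMM factors, filterByExpr with its default minimum count of 10 and total of 15), which kept 16731 genes. Adjusted p is Benjamini-Hochberg over these genes, with a threshold of 0.05. The design set before the data were examined had no block. The replicate number as a block was set as an alternative at the same time, because both groups carry the numbers 1, 2 and 3. Samples of one number deviated together from their group means, with correlations across genes of 0.662, 0.732 and 0.632 for numbers 1, 2 and 3. Samples of different numbers had correlations between -0.541 and -0.107. Deviations from a group mean sum to 0, so these negative values follow in part from the positive ones. A correlation over 0.1 in every pair was the criterion for treating the numbers as pairs, so the blocked values stand beside the others. The criterion was set in advance, but the correlations were first computed in the same run as the calls of both fits. The common dispersion was 0.106 without the block and 0.0134 with it. No pair of replicates of a group agreed within counting noise (chi-square of 30.7 to 131 per degree of freedom).

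Named genes were chosen by a rule set before the data were examined. It takes the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, leaving out clone names. It also takes up to 3 called members of each list, or up to 2 members as values where none was called, and 8 genes named in advance (GUCY1A3, GUCY1B3, PRKG1, PDE5A, CXCR4, DPP4, CD34 and CYP1A1). The rule was applied to the fit with the block, because 0 genes passed without it. That choice was made after the calls of both fits were seen. In all 32 gene lists set in advance were tested with camera (preset correlation 0.01, lists with at least 5 tested members, adjusted over the lists), with an estimated correlation and with fry as alternatives. Camera calls are those without the block unless stated. SE is the fold change divided by the square root of the F statistic. CPM values use TMM library sizes.

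The gene and list tests were run on simulated data first, with the real means per replicate number, library sizes and blocked dispersions. For riociguat against DMSO, in 16397 genes tested, 50 genes were changed at each of 4 sizes. With the block, 98, 76, 74 and 82% of those changed by 2, 1, -1 and -2 on the log2 scale were called, and 21 of the 16202 tested unchanged genes were called. Changed genes that the filter removed count as not called. Without the block the shares were 58, 2, 4 and 42%, and 0 unchanged genes were called. In a run on 16731 genes, 4 of 4 lists shifted by 0.5 and 0 of 28 others were called, with and without the block. That shift exceeds the median of every real list (at most 0.40, the AHR list without the block), so smaller shifts were not tried. Camera with an estimated correlation and fry were not run on simulated data. The simulated genes were drawn independently and changed alike in each pair. The runs therefore do not show how often lists of correlated genes are called falsely. In the real data the estimated correlation with the block was 0.456 for the MYC target list and 0.725 for the ribosomal protein list.

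Alternatives set in advance were DESeq2 (1.42.0), RLE and upper-quartile factors, no filter, a filter of 5 CPM in 3 samples, the likelihood ratio test, limma-voom (limma 3.58.1), an adjusted p under 0.01, an absolute log2 fold change of at least 1, the block, and leaving out each of the 6 samples. The same alternatives within the blocked fit, and leaving out each replicate pair there, were chosen after the data were seen. The self-made figures used matplotlib 3.10.9. Depth ranged from 17122524 to 29390228 counts per sample, and CPM below about 1 rest on few reads.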

Results

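CD34+ hematopoietic stem and progenitor cells isolated from human cord blood were kept for 16 h with 10 µM riociguat or with the DMSO vehicle. Riociguat stimulates soluble guanylate cyclase, the nitric oxide receptor that makes cGMP. Gene expression was measured by RNA sequencing in 3 samples of each group. The gene counts summed to 20173758, 29390228 and 26301393 in DMSO replicates 1, 2 and 3, and to 17122524, 23732080 and 23450857 in riociguat replicates 1, 2 and 3. Each riociguat library was smaller than the DMSO library of its number. Mitochondrially encoded genes took 11.3, 5.80 and 9.12% of the counts in the DMSO samples and 12.8, 7.13 and 7.99% in the riociguat samples. These shares followed the replicate number more than the treatment. The comparison of riociguat with DMSO asks which transcripts differed after exposure to the drug.

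Riociguat raised the transcript of renin (REN), the protease that starts the angiotensin cascade, more than that of any other gene named here. REN went from 0.852 ± 0.703 to 78.6 ± 56.0 CPM (count scaled to library size; mean ± SD, n = 3 per group), a log2 fold change of 6.54 ± 0.16 (SE). The secreted neuropeptide precursor VGF rose from 18.6 ± 4.20 to 177 ± 77.7 CPM, by 3.18 ± 0.15 on the log2 scale. The cytokine IL11 rose by 4.07 ± 0.30. NPTX1, a neuronal pentraxin, FAM163A, the galectin LGALS12, IGLON5 and the hyaluronan synthase HAS1 rose by log2 fold changes of 4.65, 4.25, 4.09, 3.73 and 3.36. Like that of REN, the DMSO means of FAM163A, LGALS12 and IL11 (0.200, 0.728 and 0.489 CPM) rest on few reads, so the size of these rises is uncertain. Among the falling genes, HEMGN, a nuclear protein of hematopoietic progenitors, went from 32.5 ± 10.1 to 11.0 ± 3.23 CPM, a log2 fold change of -1.56 ± 0.14.

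These calls came from edgeR's quasi-likelihood test with the replicate number as a block. That fit called 286 of 16731 tested genes, 228 higher and 58 lower with riociguat, at a Benjamini-Hochberg adjusted p under 0.05. On simulated data the same fit gave a larger share of false calls than 0.05. The same test without the block, which was the design set in advance, called 0 genes. It had a lowest adjusted p of 0.200 and 471 genes at an unadjusted p under 0.05. Other splits of the 6 samples into 3 and 3 gave 14 to 3955 such genes. Those that part all 3 replicate pairs, as the real split does, gave at most 138. Without the block, DESeq2 called 72 genes, edgeR's likelihood ratio test 58 and limma-voom 0. The quasi-likelihood test called 10 without riociguat replicate 1. With the block the number was 182 without replicate pair 2 and 3288 without replicate pair 1. The fold changes of the leading genes hardly moved between the fits (REN 6.45 ± 0.79 without the block), while their standard errors did. The word rose or fell below refers to the fit with the block. Of the 286 genes, 285 had the same sign in all 3 replicate pairs. The blocked test favours genes whose pairs agree, so the shared sign follows largely from the selection. In 184 of the 286 the groups did not overlap, as in 7.50% of all tested genes. Chance gives no overlap in 10% of unchanged genes if all 6 samples vary independently, which the shared replicate numbers speak against.

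**Figure D1:**
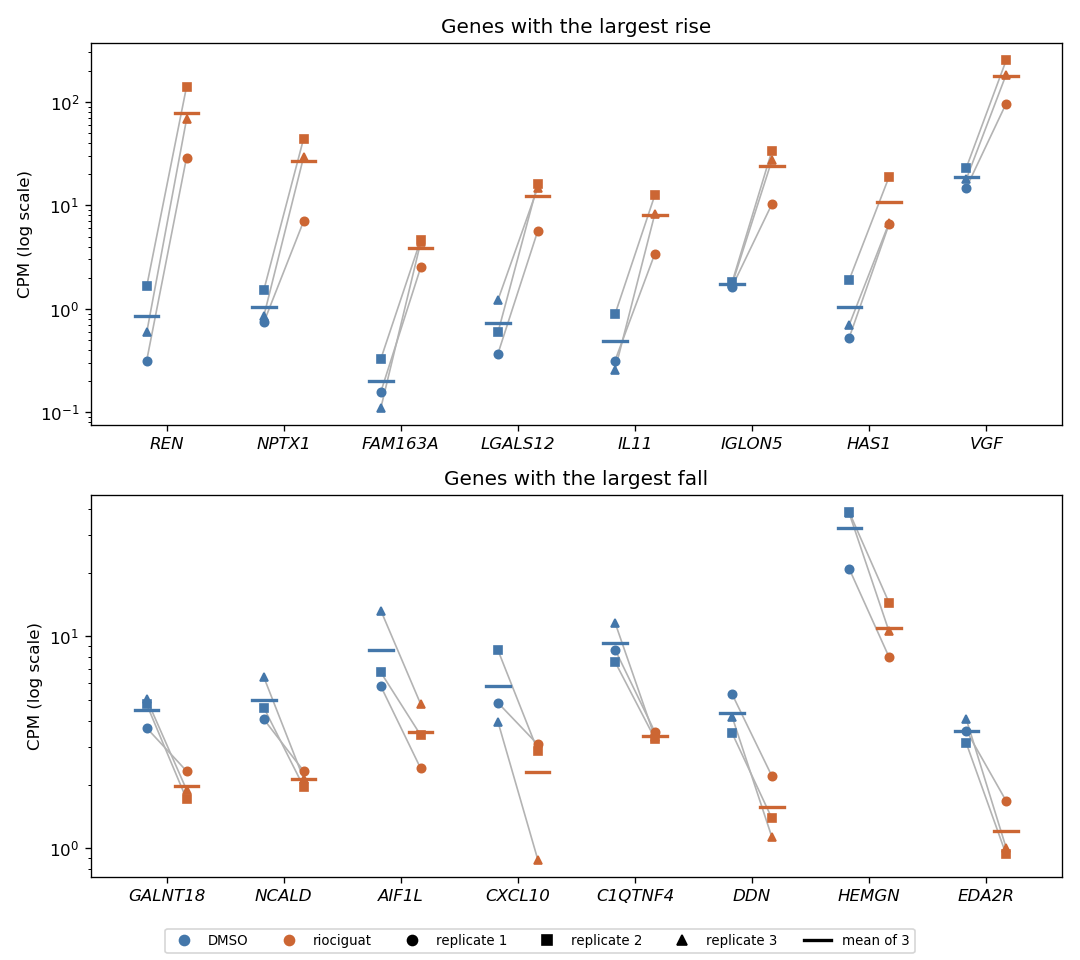
CPM on a log scale in each of the 3 DMSO (blue) and 3 riociguat (orange) samples for the 8 genes with the largest rise and the 8 with the largest fall in the fit with the block; marker shapes give the replicate number, grey lines join samples of one number and bars are means. The naming rule took only genes without overlap between the groups. The DMSO mean of REN was 0.852 CPM against 78.6 CPM with riociguat.

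The adjusted p was 1.25e-07 for REN, 2.02e-05 for VGF, 5.40e-05 for NPTX1 and 0.000562 for HEMGN (edgeR, replicate block). The REN gene (ENSG00000143839.14, protein coding) lies on chromosome 1 at 204154819 to 204190324 of hg38. VGF (ENSG00000128564.6) lies on chromosome 7 at 101162509 to 101165593. HEMGN (ENSG00000136929.12) lies on chromosome 9 at 97926791 to 97944856. The other genes with the largest falls were EDA2R, a receptor of the tumour necrosis factor receptor family (-1.62 ± 0.28), DDN (-1.50 ± 0.25) and C1QTNF4 (-1.44 ± 0.19). They were followed by the interferon-induced chemokine CXCL10 (-1.43 ± 0.28), AIF1L (-1.25 ± 0.18), NCALD (-1.24 ± 0.23) and GALNT18 (-1.21 ± 0.25). The calls of NCALD and GALNT18 ended without replicate pair 2 (adjusted p = 0.0509 and 0.221) and without replicate pair 3 (adjusted p = 0.103 and 0.0790). REN, DDN and 9 other named genes overlap a gene on the opposite strand in the deposited table, 8 named genes overlap one on the same strand. Whether the counting used strand is not given in the sources used here.

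Of the 32 lists 14 passed camera without the block and 14 with it, 13 of them in both. With an estimated correlation 0 lists passed in either fit (lowest adjusted p = 0.391 without the block and 0.324 with it), and with fry 0. Leaving out 1 sample from the fit without the block unbalances the replicate numbers, so calls that end or turn there also hold differences between the numbers. With the block, 10 of the 14 called lists kept their call and direction at the preset correlation without each replicate pair in turn, while all 14 lost it with an estimated correlation and with fry. These 10 were the CREB, cytokine feedback, glycolysis, AHR, NF-kB, TGF-beta, mast cell, interferon, MYC target and oxidative phosphorylation lists. With the block, the AHR, mast cell, interferon and cytokine feedback lists had estimated correlations of -0.056, -0.042, -0.022 and -0.027, below the preset 0.01. They still lost their calls (camera adjusted p = 0.324 for each), so correlation between genes alone does not account for the loss. With 6 samples that form of camera also has few degrees of freedom. With the block even the CREB list, with a camera adjusted p of 2.63e-15 at the preset correlation and an estimated correlation of 0.028, reached only 0.324. A call lost in that form of camera therefore neither separates the lists nor speaks for them.

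Of 28 tested members of the CREB and immediate early list 10 rose, 0 fell and 18 did not pass. Adjusted over the list alone 17 rose and 1 fell. The nuclear receptors NR4A2 and NR4A3 rose by 1.29 ± 0.17 and 1.18 ± 0.19, both on the log2 scale with the SE. CREM, a cAMP-responsive transcription factor, rose from 21.6 ± 13.02 to 40.0 ± 12.8 CPM. The list lay above other genes (median log2 fold change 0.36; camera adjusted p = 3.05e-13; adjusted p = 0.391 with an estimated correlation). Its camera call held without each of the 6 samples in turn.

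Cytokine receptor and signalling feedback genes showed 6 rises and 1 fall among 32 tested members (camera adjusted p = 0.0112; adjusted p = 0.391 with an estimated correlation). There were 9 rises and 3 falls adjusted over the list alone. Among the 6 rising members, EGR1 and DUSP4 were also counted as rising in the CREB list. The cytokine LIF rose by 1.72 ± 0.12, the stem cell factor receptor KIT by 0.91 ± 0.11 and the signalling inhibitor SPRY4 by 1.21 ± 0.17. Glycolysis and hypoxia genes showed 5 rises and 0 falls among 39, and the same numbers adjusted over the list alone (camera adjusted p = 0.000207; adjusted p = 0.599 with an estimated correlation). In that list DDIT4, a stress-induced inhibitor of mTORC1, rose from 23.1 ± 5.25 to 91.2 ± 12.7 CPM. The hypoxia-inducible factor EPAS1 rose by 1.33 ± 0.19 and the glucose transporter SLC2A3 by 0.80 ± 0.09. Both list calls ended without DMSO replicate 1 (camera adjusted p = 0.0882 for each). The cytokine list also lost its call without riociguat replicate 2 (0.0695).

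NF-kB and inflammatory genes showed 4 rises and 0 falls among 38, and 13 rises adjusted over the list alone (camera adjusted p = 0.00181; adjusted p = 0.701 with an estimated correlation). PTGS2, the inducible cyclooxygenase, rose by 1.06 ± 0.19, and the chemokines CXCL3 and CXCL8 by 0.78 ± 0.15 and 0.50 ± 0.10. The TGF-beta response list lay higher with 1 rise among 24, that of THBS1, a matrix glycoprotein (1.82 ± 0.10), and 2 adjusted over the list alone (camera adjusted p = 0.0398; adjusted p = 0.599 with an estimated correlation). Of 15 targets of the aryl hydrocarbon receptor (AHR), 2 rose, the growth factor EREG by 0.93 ± 0.18 and the cytochrome P450 CYP1A1 by 0.75 ± 0.15. Adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 0.0398; adjusted p = 0.410 with an estimated correlation). Without replicate pair 2 the calls of EREG, CXCL3 and CXCL8 ended (adjusted p = 0.1002, 0.160 and 0.0597). Those of EREG and CXCL8 also ended without replicate pair 3 (adjusted p = 0.211 and 0.0603). Under the stricter filter the calls of CXCL8 and CYP1A1 ended (adjusted p = 0.0539 for each), and that of CXCL8 also with no filter (0.0550). The NF-kB list lost its camera call without DMSO replicate 3 (adjusted p = 0.726), riociguat replicate 1 (0.378) or riociguat replicate 2 (0.110). The TGF-beta list lost it without DMSO replicates 1 or 3 (0.189 and 0.368) or riociguat replicates 2 or 3 (0.397 and 0.0779). The AHR list lost it without DMSO replicates 1 or 3 (0.148 and 0.151) or riociguat replicates 1 or 2 (0.135 and 0.110).

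Interferon response genes split. Of 37 tested members 5 fell, among them CXCL10. The 3 that rose were the guanylate-binding proteins GBP4 (1.21 ± 0.11), GBP5 (0.93 ± 0.10) and GBP2 (0.71 ± 0.12). Adjusted over the list alone 16 fell and 3 rose. The list as a whole lay lower (median -0.28; camera adjusted p = 0.0398; adjusted p = 0.763 with an estimated correlation). Its direction turned without DMSO replicate 1 (adjusted p = 0.872), and its call ended without DMSO replicate 2 (0.0761), riociguat replicate 2 (0.110) or riociguat replicate 3 (0.825). With the block it was lower (camera adjusted p = 0.000865; adjusted p = 0.324 with an estimated correlation), with medians of -0.17, -0.32 and -0.28 in pairs 1, 2 and 3. The call of GBP2 ended without replicate pair 2 (adjusted p = 0.0946). Counts of the GBP genes are uncertain where reads match several of these related genes.

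The MYC target and ribosome biogenesis list lay lower with riociguat (median log2 fold change -0.22; camera adjusted p = 2.15e-08; adjusted p = 0.519 with an estimated correlation). MYC was its 1 falling member of 36, from 461 ± 86.9 to 318 ± 2.84 CPM, and 0 members rose, over all genes and adjusted over the list alone. The MYC call ended without replicate pair 2 (adjusted p = 0.349), under the stricter filter (0.0732), with no filter (0.0505) and with upper-quartile factors (0.0515). The nuclear oxidative phosphorylation list of 45 genes had a median of -0.12 with 0 members called, over all genes and adjusted over the list alone (camera adjusted p = 0.00662; adjusted p = 0.763 with an estimated correlation). It lost its camera call without DMSO replicate 1 (0.667) or riociguat replicates 2 or 3 (0.308 and 0.339). Its members CYC1 and NDUFV1 had log2 fold changes of -0.35 ± 0.11 and -0.25 ± 0.09. The 60 cytosolic ribosomal protein genes had 0 calls by either adjustment and a median of -0.06 (camera adjusted p = 0.0398; adjusted p = 0.887 with an estimated correlation). RPL7A was at -0.17 ± 0.10 and RPS7 at -0.14 ± 0.09. This list turned upward without DMSO replicate 1 (adjusted p = 0.667), riociguat replicate 2 (0.776) or riociguat replicate 3 (0.754). With the block it passed (0.00380; adjusted p = 0.753 with an estimated correlation), but not without replicate pair 2 (0.0635) or pair 3 (0.585). Reads of ribosomal protein genes can also match their processed pseudogenes.

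Heat shock genes also lay lower, with 0 of 21 called by either adjustment (median -0.15; camera adjusted p = 0.0398; adjusted p = 0.410 with an estimated correlation). FKBP4 and HSPA4L had log2 fold changes of -0.31 ± 0.09 and 0.72 ± 0.22. Unfolded protein and amino acid response genes lay lower too (median -0.14; camera adjusted p = 0.0398; adjusted p = 0.599 with an estimated correlation). Of 35, the glutathione-degrading enzyme CHAC1 fell by 1.07 on the log2 scale, while DDIT4 and the transcription factor ATF3 (0.65 ± 0.13) rose. Adjusted over the list alone 9 fell and 4 rose. Without replicate pair 2 the calls of CHAC1 and ATF3 ended (adjusted p = 0.316 and 0.212). The response list lost its camera call without DMSO replicate 2 (adjusted p = 0.508) or riociguat replicates 1 or 3 (0.196 and 0.169). The heat shock list lost it without each sample in turn except DMSO replicate 3 (0.0554 to 0.152). With the block the response list passed (0.0437), but not without replicate pair 1 (0.125) or pair 2 (0.186). The heat shock list passed with the block (0.0273), but not without pair 2 (0.122). Both lost the blocked call with an estimated correlation (adjusted p = 0.479 for each). The ATF3 call also ended under the stricter filter (adjusted p = 0.0504).

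**Figure D2:**
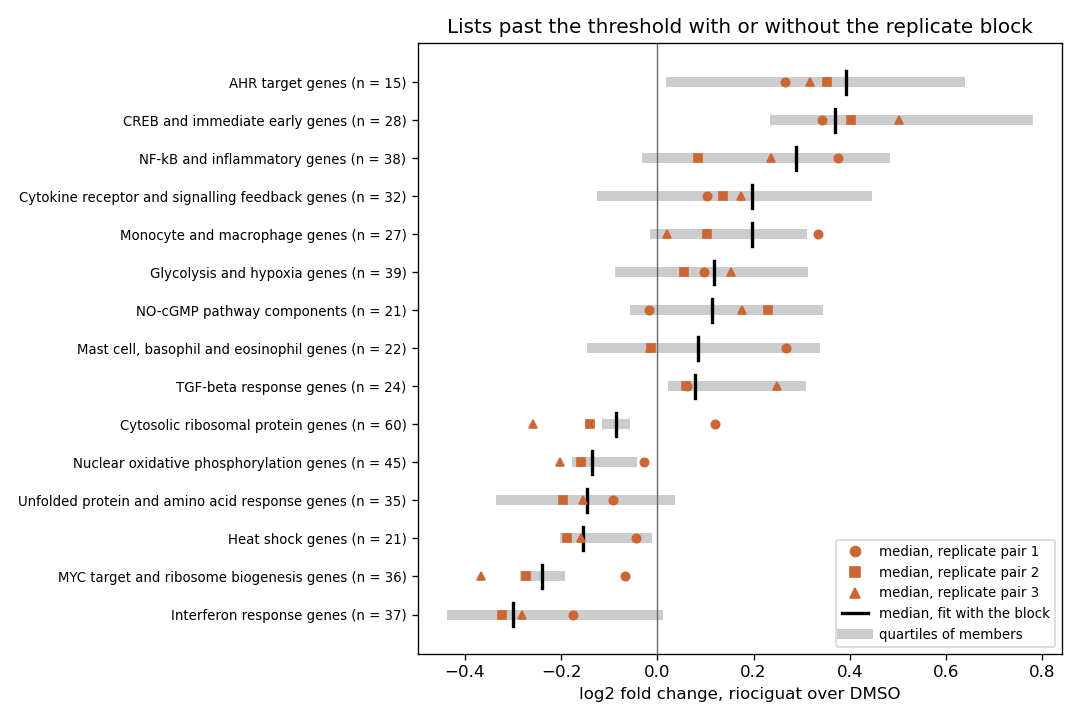
Median log2 fold change of the members of each list that passed camera with or without the replicate block, in each replicate pair (orange markers) and in the fit with the block (black bars), with the quartiles of the members in that fit (grey). The MYC target and ribosome biogenesis list lay below 0 in each pair, and the cytosolic ribosomal protein list lay above 0 in pair 1 and below 0 in pairs 2 and 3.

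Among the components of nitric oxide and cGMP signalling, the drug's target pathway, 2 of 21 rose and 0 fell, and 3 rose adjusted over the list alone. The phosphodiesterases PDE1C and PDE3B rose by 1.91 ± 0.34 and 1.07 ± 0.21. The guanylate cyclase subunits GUCY1A3 and GUCY1B3 had log2 fold changes of -0.38 ± 0.13 and 0.05 ± 0.10 (edgeR adjusted p = 0.224 and 0.860). The cGMP-dependent kinase PRKG1, at a mean of 1.03 CPM in DMSO, was at 0.02 ± 0.46 and the cGMP-degrading PDE5A at 0.54 ± 0.30 (adjusted p = 0.993 and 0.441). The list passed without the block (camera adjusted p = 0.0398; adjusted p = 0.410 with an estimated correlation) and not with it (camera adjusted p = 0.150). It did not pass without DMSO replicates 1 or 2 (0.148 and 0.114) or riociguat replicates 2 or 3 (0.110 and 0.190). The PDE3B call ended with DESeq2 (adjusted p = 0.139) and under the stricter filter (0.0579), and the PDE1C call ended without replicate pair 3 (adjusted p = 0.0783).

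Genes for homing and adhesion and for the stem and progenitor state moved in both directions. The chemokine receptor CXCR4 rose from 221 ± 142 to 320 ± 109 CPM, by 0.66 ± 0.13 within pairs on the log2 scale. DPP4, the peptidase that cleaves its ligand, rose by 1.45 ± 0.25, while the fucosyltransferase FUT7 fell by 0.95. These were 2 rises and 1 fall among 34 homing genes (camera adjusted p = 0.582), with 4 rises and 5 falls adjusted over the list alone. Of 35 stem and progenitor genes 3 rose and 3 fell (camera adjusted p = 0.618). KIT and the transcription factor GATA2 (0.50 ± 0.08) rose and SPINK2 (-0.71 ± 0.11) fell. Adjusted over the list alone 9 rose and 7 fell. The median of each of these lists lay within 0.02 of 0 and differed in sign from its test or mean in at least 1 of the fits. CD34 itself had a log2 fold change of -0.26 ± 0.10 (adjusted p = 0.251). Without replicate pair 2 the calls of DPP4, CXCR4, GATA2 and SPINK2 ended (adjusted p = 0.111, 0.0846, 0.413 and 0.123). That of CXCR4 also ended under the stricter filter (0.0642) and with no filter (0.0567).

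Markers of other blood lineages were mostly not called. Mast cell, basophil and eosinophil genes lay higher (camera adjusted p = 0.0398; adjusted p = 0.599 with an estimated correlation), with 4 of 22 rising, over all genes and adjusted over the list alone. These were the interleukin 33 receptor IL1RL1, from 58.1 ± 34.5 to 211 ± 122 CPM, KIT, GATA2 and the histidine decarboxylase HDC (0.74 ± 0.10), whose call ended without replicate pair 2 (adjusted p = 0.0786). The list lost its camera call without DMSO replicates 2 or 3 (0.103 and 0.259) or riociguat replicate 1 (0.735). Its median log2 fold change was 0.27, -0.013 and -0.014 in pairs 1, 2 and 3. Of 25 erythroid genes, the carbonic anhydrase CA2 (3.01 ± 0.23) and GYPC (0.48 ± 0.08) rose and HEMGN fell, with 2 rises and 4 falls adjusted over the list alone (camera adjusted p = 0.507). The megakaryocyte and platelet list had 1 rise among 24, that of THBS1, and 2 rises and 2 falls adjusted over the list alone (camera adjusted p = 0.793). Among 24 B lymphoid genes, the surrogate light chain gene IGLL1 fell by 1.03 and IL7R rose by 0.48 ± 0.09, with the same numbers adjusted over the list alone (camera adjusted p = 0.466). GZMB, a granule protease, was the 1 called gene of both the 24 T and NK cell genes and the 26 dendritic cell genes (0.58 ± 0.10; camera adjusted p = 0.793 for each list). Adjusted over the list alone the first had 2 rises and 1 fall and the other 3 rises and 1 fall. Monocyte and macrophage genes had 0 of 27 called, or 2 rises adjusted over the list alone, with FCGR3A at 0.62 ± 0.16 and FCN1 at 0.55 ± 0.13. The list passed with the block (camera adjusted p = 0.0185; adjusted p = 0.479 with an estimated correlation) but not without it (0.462) or without replicate pair 1 (0.344). The 21 neutrophil precursor genes had 0 calls, or 2 rises adjusted over the list alone, with SRGN at 0.65 ± 0.16 and RNASE3 at 0.78 ± 0.19 (camera adjusted p = 0.462). Of 17 endothelial and stromal genes EMCN rose by 0.97 ± 0.17, with 4 rises and 3 falls adjusted over the list alone (camera adjusted p = 0.480). The erythroid, neutrophil and chromatin lists also had medians within about 0.05 of 0 that differed in sign from their test or mean in at least 1 of the fits. Without replicate pair 2 the calls of GYPC, IL7R and GZMB ended (adjusted p = 0.316, 0.350 and 0.203).

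The lists for the cell cycle, p53 targets, apoptosis, chromatin, oxidative stress, cholesterol biosynthesis and mitochondrially encoded genes did not pass camera. Of 36 S phase genes the ribonucleotide reductase subunit RRM2 rose by 0.44 ± 0.09 (camera adjusted p = 0.204). Of 35 G2 and M phase genes 0 were called, with BUB1B at -0.21 ± 0.10 and CDC20 at -0.24 ± 0.12 (0.757). The 30 cell cycle inhibitor and p53 target genes had 0 calls, or 4 rises and 2 falls adjusted over the list alone, with CDKN1A at 0.47 ± 0.11 and PLK2 at 1.02 ± 0.23 (camera adjusted p = 0.204). TNFSF10, the death ligand TRAIL, rose by 0.69 ± 0.13 among 29 apoptosis regulators (0.153), of which 4 rose and 2 fell adjusted over the list alone. The DNA methyltransferase DNMT3B fell by 0.56 among 35 chromatin regulators (camera adjusted p = 0.650). The ferritin heavy chain gene FTH1, which has many pseudogene copies, rose by 0.71 ± 0.08 among 28 oxidative stress genes (0.793). The 32 cholesterol biosynthesis genes had 0 calls, with PMVK at -0.50 ± 0.13 and FASN at -0.30 ± 0.10 (camera adjusted p = 0.462). The 15 mitochondrially encoded genes had 0 calls, with MT-RNR2 at 0.25 ± 0.10 and MT-CO1 at 0.19 ± 0.11 (0.618). The remaining lists had the same counts adjusted over the list alone. Without replicate pair 2 the calls of RRM2, TNFSF10 and DNMT3B ended (adjusted p = 0.656, 0.415 and 0.322), and that of DNMT3B also under the stricter filter (0.0513).

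In the authors' deposited table, 506 of 18707 genes had an FDR under 0.01, 353 higher and 153 lower. All 286 genes called with the block were among those of the authors' deposited table, with the same direction. The authors' values rest on the same counts, so this overlap is no independent support for the calls. The authors' deposited table gave REN a log2 fold change of 6.53 with an FDR of 9.42e-231. Its log2 fold changes differed from those of edgeR's likelihood ratio test with the block, over all genes, by a median of 0.000106, and from the test without the block by a median of 0.0173. That test with the block called 506 genes at an adjusted p under 0.01, and 506 of these were among the 506 of the authors' deposited table.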

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

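The alternatives within the fit with the replicate block were chosen after the data were seen. Without the block the count of 0 called genes held in edgeR with RLE or upper-quartile factors, no filter, a stricter filter and limma-voom. DESeq2 called 72 (68 higher, 4 lower), the likelihood ratio test 58 (55 higher, 3 lower) and the replicate block 286 (228 higher, 58 lower). Leaving out single samples gave 0 to 10 genes, all 10 of them higher and found without riociguat replicate 1. With the replicate block, DESeq2 called 439 (133 lower), the likelihood ratio test 876 (568 higher, 308 lower), an adjusted p under 0.01 left 98 (93 higher, 5 lower), an absolute log2 fold change of at least 1 left 137 (122 higher, 15 lower), and the stricter filter left 31 lower genes. Leaving out a replicate pair gave 182 (without pair 2) to 3288 (without pair 1) genes, 159 to 1762 higher and 23 to 1526 lower. All 286 genes were among the 3288, and 155 among the 182. Of 56 called named genes, 0 changed direction in the blocked alternatives, 31 lost their call at an adjusted p under 0.01 and 24 at an absolute log2 fold change of at least 1. Without pair 2, 20 lost their call, as did 5 without pair 3, 7 under the stricter filter (PDE3B, CYP1A1, CXCR4, ATF3, CXCL8, MYC and DNMT3B), 3 with no filter and 1 each with upper-quartile factors (MYC) and DESeq2 (PDE3B). Stricter thresholds end calls by construction, and the causes of the other losses were not tested.

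The 14 list calls held with RLE factors and with no filter, with and without the block. With an estimated correlation 0 lists passed, and with fry 0, in both fits. Fry's mixed test, which asks only whether members change in either direction, passed 3 lists without the block and 19 with it. The block ended 1 call, that of the NO-cGMP list, and added the monocyte list. Leaving out single samples gave 6 to 12 called lists in all, and 5 to 10 of the 14 calls were kept. They were fewest, 5, without DMSO replicate 1 (2 turned) and without riociguat replicate 2 (1 turned). The CREB and MYC lists kept their calls in all 6. With the block 12, 11 and 13 of the 14 calls were kept without pairs 1, 2 and 3, and 0 turned. The calls that ended were those of the monocyte list without pair 1, unfolded protein without pairs 1 or 2, heat shock without pair 2 and ribosomal protein without pairs 2 or 3. Directions turned as follows in fits without the block, with the range of camera's adjusted p over the 6 leave-outs: ribosomal protein 6.30e-13 to 0.776, interferon 1.50e-06 to 0.872, B lymphoid 0.000269 to 0.754, monocyte 0.000336 to 0.854, stem 0.00357 to 0.588, mitochondrially encoded 0.0134 to 0.431, apoptosis 0.0225 to 0.962, oxidative stress 0.0779 to 0.872, cholesterol 0.0934 to 0.918, endothelial 0.0935 to 0.877, dendritic 0.119 to 0.876, homing 0.150 to 0.964, megakaryocyte 0.202 to 0.920, T and NK 0.338 to 0.965 and G2 and M phase 0.667 to 0.975. Endothelial and T and NK lists also turned with no filter (0.966 for both). With the block, leaving out pairs turned only lists that were not called, the mitochondrially encoded (6.62e-08 to 0.828), neutrophil (0.0852 to 0.828), endothelial (0.138 to 0.713), oxidative stress (0.180 to 0.720), stem (0.181 to 0.802, and 0.961 with no filter) and homing lists (0.720 to 0.900).

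Log2 fold changes that turned without single samples, none called in those fits, ranged from -0.47 to 1.71 for FCGR3A, -0.066 to 1.04 for CXCL8, -0.34 to 1.31 for IL7R, -0.30 to 0.75 for MT-RNR2, -0.16 to 0.47 for MT-CO1, -0.29 to 0.34 for GUCY1B3, -0.51 to 0.82 for PRKG1 and -0.35 to 0.0054 for RPS7. PRKG1 was at -0.11 with limma-voom. With the block and pairs left out they ranged from -0.018 to 0.089 for GUCY1B3 and -0.61 to 0.45 for PRKG1, which was at -0.084 with DESeq2. The causes were not tested.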

Other observations

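The tests of the size of the response in pair 1 and of the mast cell list were chosen after their results had been seen in part; the others were set before. The phosphodiesterase genes were picked as a family after the calls were seen. Of 18 tested, 5 rose and 0 fell in the fit with the replicate block. Besides PDE1C and PDE3B these were PDE7B (3.07 ± 0.42), PDE4B (1.58 ± 0.30) and PDE4A (0.85 ± 0.16, log2 fold change ± SE), whose enzymes degrade cAMP. PDE4D had a log2 fold change of 1.02 ± 0.22 (edgeR adjusted p = 0.0596). Other called genes outside the naming rule, also picked after their values were seen, were the secretory granule protein PTPRN (2.99), the protease ADAMTS1 (3.13), the growth factor AREG (2.91) and the transcription factor MYCN (-0.57).

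Samples differed more by replicate number than by treatment. In the fit with both terms 6892 of 16731 genes differed between the numbers at an adjusted p under 0.05. Among the lists, 15 of 15 mitochondrially encoded genes and 22 of 24 B lymphoid genes did so.

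No number of splits available here could bring the share of splits as large as the real one under 0.05. Without the block the real split called 0 genes and the highest other split 0, so that 10 of 10 splits gave as many, and it called 14 lists against a highest other of 11, so that 1 of 10 did. Of the 10 splits, 4 part all 3 replicate pairs as the real one does, and the others of that kind gave at most 4 lists, while the 6 that part 1 pair, and so set replicate numbers against each other, gave 7 to 11. With the block, 1 of 4 labellings that exchange treatments within pairs, the real one, gave 286 genes or more, and the highest other gave 0. At an unadjusted p under 0.05 the real labelling gave 2447 genes, and exchanging pair 1, 2 or 3 gave 1738, 44 or 116. For lists the real labelling gave 14 and the highest other 6 (1 of 4).

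More genes passed when replicate pair 1 was left out, 3288 against 286. Its lower depth does not account for this: with pairs 2 and 3 thinned to the totals of pair 1, the lowest of 5 draws still called 2549. A smaller response in pair 1 may be part of the cause. Over the 100 genes with the smallest p in the other pairs, the held-out slope was 0.642 (95% bootstrap interval over genes 0.554 to 0.717) for pair 1, against 1.06 (1.01 to 1.11) and 1.14 (1.07 to 1.22) for pairs 2 and 3. The slope of pair 1 covers only those 100 genes, of which 94 had the same sign in that pair. The intervals treat genes as independent and do not measure how a single pair of samples varies. Each slope was taken against the mean of the other pairs, over genes picked anew for each pair. For pairs 2 and 3 that mean includes pair 1, so a smaller response there also raises their slopes and widens the contrast. Over the 10420 genes with a mean log2 CPM of at least 3, pair 1 also differed in pattern. Its fold changes correlated at 0.384 with pair 2 and 0.170 with pair 3, against 0.769 between pairs 2 and 3. A smaller size need not be the only difference. What the numbers mark is open, so no biological explanation was tested.

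The mast cell, basophil and eosinophil list passed camera as higher with riociguat. Its median log2 fold change lay above 0 only in pair 1 (0.27, against -0.013 and -0.014 in pairs 2 and 3). Whether more cells of these lineages contributed cannot be told apart from regulation within other cells. More such cells would raise their abundant transcripts together, but the 15 members with a mean log2 CPM of at least 3, called or not, went both ways, with a median log2 fold change of 0.070 (quartiles -0.21 and 0.42; 8 above 0 and 7 below). Of the 4 called genes 2, KIT and GATA2, are also on the stem and progenitor list. Isolation by CD34 selects against mature cells of these lineages, but the purity of the samples is not given in the sources used here. It therefore does not settle the question.

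The MYC target and ribosome biogenesis list and the nuclear oxidative phosphorylation list were lower. They had medians of -0.24 and -0.14 with the block, against -0.07 and -0.06 for 10000 random lists each, matched on length and expression. Among those random lists they lay at percentiles 0 and 0.07. The random lists were drawn gene by gene, while the estimated correlations within the real lists were 0.456 and 0.215 with the block. The percentiles therefore leave out shared variation between members, and cannot exclude a trend with gene length joined with it. The first list had medians of -0.067, -0.273 and -0.366 in pairs 1, 2 and 3, so the lower median was not found in 1 pair only. The 95% bootstrap interval in pair 1 was -0.13 to -0.02. It treats genes as independent and does not measure how a single pair of samples varies. The pair 1 value was also about that of the matched random lists over all pairs (-0.07), so whether pair 1 shared the shift cannot be told. The oxidative phosphorylation list was at -0.029 in pair 1 (interval over genes -0.07 to 0.05), so whether that pair shared the shift cannot be told apart from no change there. An effect of riociguat stays open for both lists, since the splits above are too few to set chance aside.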
